A study of Rattus norvegicus with 59 samples.

How the data were processed

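Total RNA from 5 brain regions (frontal cortex, striatum, hippocampus, amygdala and nucleus accumbens) of 12 adult male rats was measured on a 3′-biased Affymetrix rat expression array. The rats were 6 of the inbred alcohol-preferring line (iP) and 6 of the inbred alcohol-non-preferring line (iNP). Per the labels' protocols, each rat's RNA was labelled with biotin and hybridised separately, so every array is 1 region of 1 rat. In all 59 arrays were analysed; cortex of iP animal 6 was not analysed here. Line and region came from the sample titles and the genotype label. The source name gives the iNP line for all 59 arrays and was not used.

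The deposited values are intensity values per probe set on a linear scale, as the authors' processing gave them. The program that made them is not given in the sources used here. The 2% trimmed mean of each array lay between 998 and 999, so the values were already scaled to a common level, and no further scaling was applied. Signals under 16 were set to 16 and all values were log2 transformed. Of 8799 probe sets, 59 control probe sets were left out, together with the 40% with the lowest mean, which left 5244 probe sets. Among all probe sets that are not controls, 7006 carry 1 gene symbol, 308 several and 1426 none. Of those with 1 symbol, 6985 were matched by gene ID to the rat GRCr8 gene table, and no symbol changed. No coordinates are given, since the array annotation names no genome build. Arrays hold no read depth, and the number of animals limits the precision.

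Line differences (iP minus iNP) were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend of the variance. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, with two-sided tests. Each region was fitted alone. For the difference over all regions, each animal's regions were averaged after removing the level of each region, so that the animal was the replicate. The line by region interaction was a moderated F test with the animal as a fixed block. Each region was set against the mean of the other 4 with the animal as a fixed block, with calls at an absolute log2 difference over 1; members of the region marker lists were counted at the adjusted p alone. The pairing within animals follows from the animal numbers in the titles; it does not rest on the correlation of residuals between regions. That had a mean of 0.0561 within animals, was below 0 in 5 of the 12 animals, and was -0.00456 between different animals, 0.0297 between different animals on the same side of a grouping seen in the data (animals 1, 2, 7 and 8 against the others) and 0.0740 between iP animals and the iNP animals numbered 6 higher.

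The design, alternatives, gene lists and rule for named genes were fixed before the data were examined. Named genes come from probe sets with 1 symbol, and the brightest probe set stands for a gene. Over all regions, the 12 largest rises and 12 largest falls among calls with no overlap between the lines are named. In each region the same rule takes 5 and 5. The 8 smallest interaction p-values, the 5 largest rises of each region, up to 4 called and 2 uncalled members of each list, and all preference candidates complete the rule. Gene lists (35, of which 34 had at least 5 tested members) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Differences in RNA quality were tested with exact permutation tests.

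One step was corrected after results had been seen. The values per animal were at first centred on 0, which left the variance trend no intensity to follow. The mean level of each probe set was then added back. The earlier form called 137 probe sets over all regions and the corrected form 139, of which 128 are shared.

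The fits were tested on simulated data with known changes, in 5 runs of 5244 probe sets. Each array was drawn independently, with no animal effect, grouping of animals or correlation between genes. The rates given here do not cover these. Over all regions, 87.8% of changes of 0.5, 98.8% of changes of 1 and 99.7% of changes of 2 (log2) were recovered, with 6.29% false calls. In cortex 75.2% of changes of 1 were recovered, with 10.8% false calls. The interaction test made 14.4 false calls per run where each group kept its own spread, and 0 where the spread was pooled.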

Results

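The arrays covered 6 iP and 6 iNP rats in each region, except cortex, which had 5 iP rats. The question was which transcripts differ in the brain between rats bred for high and for low alcohol preference. Median signal ran from 251 to 391 over the 59 arrays. In the exact permutation tests of RNA quality measures between the lines, the smallest p was 0.0649 (striatum, median signal; 0.806 after Benjamini-Hochberg adjustment over 15 tests). A pair of arrays stood apart. Cortex of iP animal 5 had a Gapdh 3′ to 5′ signal ratio of 6.14 (log2). Amygdala of iP animal 1 had a score on amygdala-high minus cortex-high genes of -1.06, where the other 11 amygdala arrays lay between 1.20 and 2.74. Cortex of iP animal 5 scored 1.31 on the same measure, and the other 10 cortex arrays lay between -1.57 and -0.95. Both arrays were kept in the comparisons. By median correlation with the arrays of each region, amygdala of iNP animals 7 and 8 was nearest accumbens. Accumbens of iP animal 4 was nearest amygdala. These arrays were kept too.

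**Figure D1:**
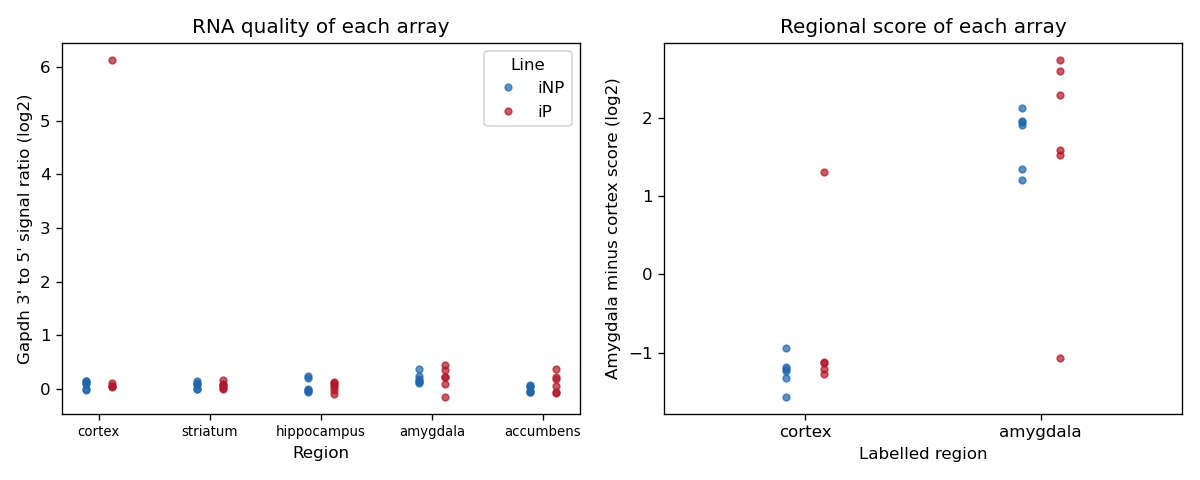
Left, log2 ratio of 3′ to 5′ Gapdh signal for each array (points) by region and line. Right, amygdala minus cortex score (log2) of each cortex and amygdala array; the cortex array at 1.31 is iP animal 5 and the amygdala array at -1.06 is iP animal 1.

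Averaged over the brain regions of each animal, the lines differed most in Hs6st1, which encodes a heparan sulfate 6-O-sulfotransferase. Its signal was higher in iP by 4.23 ± 0.20 (log2, SE; n = 6 and 6 animals; limma adjusted p = 4.09e-09). Akap11, an anchoring protein of protein kinase A, rose by 2.55 ± 0.08, and Mfsd10, a membrane transporter, by 1.97 ± 0.11. The glycolytic enzyme gene Pgk1 rose by 1.12 and Arpc4, a subunit of the actin-nucleating Arp2/3 complex, by 1.09. Tmtc3 changed by -2.25 ± 0.12, the RNA helicase gene Ddx42 by -2.18 ± 0.12 and Paqr3 by -1.71 ± 0.11. The myo-inositol transporter gene Slc5a3 changed by -1.23 and the glutathione transferase gene Gsta4 by -1.17 ± 0.05.

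In all, 139 of 5244 probe sets passed the threshold, 63 higher and 76 lower in iP. Of 10 genes of the list of sodium channels and pumps, Scn1a rose by 0.74, Scn3a changed by -0.81 and 8 did not pass, with the same counts when adjusted over the list alone. As a list they did not pass by camera (adjusted p = 0.95; adjusted p = 0.962 with an estimated correlation). The other named rises were Cul2 (0.57), Atic (0.57), Lyz2 (0.54), Clns1a (0.53), the asparagine synthetase gene Asns (0.50) and Pcmtd1 (0.50). The other named falls were Sdhaf2 (-0.85), Lysmd4 (-0.81), Slc28a2 (-0.80), the microglial purine receptor gene P2ry12 (-0.77), Sephs2 (-0.73) and Phgdh, which encodes an enzyme of serine synthesis (-0.62). Further probe sets of Gsta4 (-0.89), Scn3a (-0.87), Lysmd4 (-1.56) and Phgdh (-0.58 and -0.53) were also called in the same direction. Those of Gsta4, Scn3a and Lysmd4 lie on the same sequence record as the named probe set, so they are not a separate check. For Phgdh, only the probe set at -0.53 lies on another record. A further Pgk1 probe set differed by 0.12 (adjusted p = 0.247), and those of Clns1a by 0.07 and 0.10, none of them called.

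**Figure D2:**
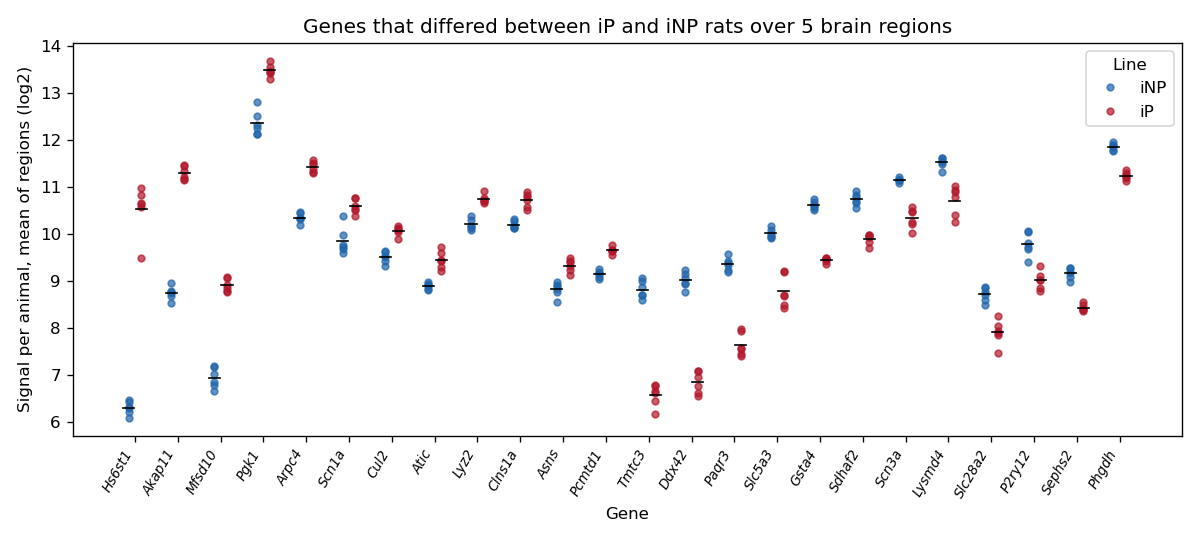
Log2 signal of each named gene per animal, averaged over its regions (points, 6 iNP and 6 iP animals), with the mean of each line (bars). Hs6st1 has a mean of 6.29 in iNP and 10.53 in iP, and no gene shown overlaps between the lines.

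Of the genes listed beforehand as candidates for alcohol preference, 6 were tested and 2 fell over all regions, also when adjusted over the list alone. These were Gsta4 and Npy, which encodes neuropeptide Y; Npy changed by -0.24 ± 0.05 (adjusted p = 0.0146). Pdyn differed by 0.02 and Grm7 by -0.04, and neither passed; Crh (0.11) and Neurod1 (-0.06) did not pass either. Drd2, Oprm1 and Htr1b were on the array but below the signal filter. As a list the candidates were lower in iP by camera (adjusted p = 0.0248), which was lost in the stricter version (adjusted p = 0.415 with an estimated correlation). It was also lost with the mean of all probe sets of a gene (adjusted p = 0.238).

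Among 18 genes of the major histocompatibility complex and antigen processing, 4 fell, 1 rose and 13 did not pass; adjusted over the list alone, 6 fell and 3 rose. RT1-A (-0.60), RT1-CE16 (-0.58), RT1-CE12 (-0.50) and the class I light chain gene B2m (-0.37) were lower, and the immunoproteasome gene Psmb8 was higher by 0.39. The names of these 3 RT1 probe sets carry the manufacturer's suffix for probe sets that match several members of a gene family, and cross-hybridisation was not measured, so the member behind each value is uncertain. The list was lower by camera (adjusted p = 0.00702; adjusted p = 0.458 with an estimated correlation). Of 6 blood cell transcripts only Hbb-b1 fell (-0.38), and adjusted over the list alone 4 fell (adjusted p = 0.00702; adjusted p = 0.533 with an estimated correlation). Of 9 endothelial and mural cell genes Pecam1 fell (-0.47), the only call also when adjusted over the list alone (adjusted p = 0.0282; adjusted p = 0.458 with an estimated correlation). Of 18 heat shock and chaperone genes Pdia4 rose (0.48), and adjusted over the list alone 2 rose (adjusted p = 0.0248; adjusted p = 0.458 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.0799).

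In cortex, Akap11 rose by 2.16 ± 0.30, Pgk1 by 1.17 ± 0.15 and Arpc4 by 1.07 ± 0.12 (n = 5 iP and 6 iNP). Paqr3 changed by -2.02, Ddx42 by -1.95, the axon guidance gene Slit3 by -1.67, Gsta4 by -1.08 and Sdhaf2 by -0.83. Hs6st1, given here after its values were seen, was higher by 3.44 ± 0.85 and was not called (adjusted p = 0.279). Its log2 signal was 5.70 on the array of iP animal 5. The other iP arrays lay between 10.72 and 11.09 and the iNP arrays between 5.72 and 7.03. There were 12 calls, 6 in each direction. Without the array of iP animal 5 there were 24.

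In striatum, Hs6st1 rose by 4.36 ± 0.18, Akap11 by 2.73 ± 0.20, Mfsd10 by 1.76, Pgk1 by 1.20 and Arpc4 by 1.02 (n = 6 and 6). Tmtc3 changed by -2.69 ± 0.27, Ddx42 by -2.08, Paqr3 by -1.54, Gsta4 by -1.35 and Slc5a3 by -1.08. Of 44 calls, 19 were higher and 25 lower in iP.

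In hippocampus, Hs6st1 rose by 4.05 ± 0.21, Mfsd10 by 2.38, Akap11 by 2.37, Pgk1 by 1.22 and Arpc4 by 1.08 (n = 6 and 6). Ddx42 changed by -2.04, Tmtc3 by -1.85, Paqr3 by -1.68, Gsta4 by -1.37 and P2ry12 by -0.93. Of 35 calls, 11 were higher and 24 lower.

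In amygdala, Hs6st1 rose by 4.28 ± 0.25, Akap11 by 2.25, Mfsd10 by 2.14, Arpc4 by 1.39 and Pgk1 by 1.10 (n = 6 and 6). Ddx42 changed by -2.79 ± 0.38, Tmtc3 by -2.06, Paqr3 by -1.88, Slc5a3 by -1.40 and Gsta4 by -1.18. Of 38 calls, 16 were higher and 22 lower. There were 22 calls without iP animal 4 and 51 without iP animal 1, whose amygdala array scored -1.06 on the amygdala minus cortex measure.

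In nucleus accumbens, Hs6st1 rose by 4.95 ± 0.24, Akap11 by 3.24, Mfsd10 by 1.65, the lysozyme gene Lyz2 by 1.04 and Arpc4 by 0.89 (n = 6 and 6). Tmtc3 changed by -2.27, Ddx42 by -1.95, Slit3 by -1.60, Paqr3 by -1.52 and Lysmd4 by -0.94. Of 30 calls, 10 were higher and 20 lower. There were 19 calls without iNP animal 9.

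No probe set passed the limma test of a line difference that varies between regions (0 calls; 242 at an unadjusted p under 0.05, where 262.2 are expected by chance). The smallest adjusted p was 0.155, for Hsd3b7 and Tom1l2. Agrn, Gria1, Mapkapk2, Lyz2, Aldh1a2 and Or4c52 had the next smallest p-values. Of the 139 probe sets called over all regions, 133 had the same sign in all 5 regions. Choosing probe sets on the mean over these regions favours a shared sign: among the 139 with the smallest p in each of 99 other splits of the animals, a reference added after the count was seen, the median was 77 and the highest 121. The log2 differences of 2 regions correlated across probe sets with a mean Pearson r of 0.356 over the 10 region pairs. Reassigning animals to lines gave a mean of 0.0897 and at most 0.288 in 100 draws. Taken singly, 2 pairs lay below the 95th percentile of their draws. These were cortex with hippocampus (r 0.166 against 0.358) and hippocampus with amygdala (0.194 against 0.247). The other pairs lay above it. The highest pair, cortex with amygdala (0.507), had a mean of 0.255 in the draws and holds both arrays that stood apart. Where the regions came from different animals, the mean r was 0.228. Each region then had only a part of its animals, which adds noise and lowers r, so that value is not comparable with the others. The mean covariance was 0.0248, and 0.0260 where the regions came from different animals, against 0.0048 in the draws. Genes are not independent replicates.

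In striatum, Rgs9 was higher than in the other regions by 3.39 ± 0.24 (log2), the enkephalin gene Penk by 2.14, the dopamine D1 receptor gene Drd1 by 2.08, Gnal by 1.99 and the substance P gene Tac1 by 1.84. Accumbens had higher Cartpt (3.09 ± 0.16), Rgs9 (2.84), Gnal (2.18), Drd1 (2.13) and Pcp4l1 (2.09). In hippocampus, Ttr, the transthyretin gene of the choroid plexus, was higher by 4.39 ± 0.35, Htr5b by 2.18, Gpr161 by 2.10, Cebpb by 1.48 and Epha7 by 1.42. Cortex had higher Tnnc2 (1.75), Dact2 (1.43), Olr59 (1.41), Pvalb (1.35) and Plcb4 (1.32). Amygdala had higher Aldh1a2 (1.83), which makes retinoic acid, Plagl1 (1.72), Trim54 (1.66), Crabp2 (1.55) and Gpc3 (1.54). For the marker lists, members were counted at an adjusted p under 0.05 alone, with no minimum size. Of 14 medium spiny neuron markers, 13 were higher in striatum (median 1.15) and 14 in accumbens (median 0.78), and of 11 hippocampal markers 9 were higher in hippocampus (median 0.78). The other marker lists did not follow their region. Of 4 cortical projection neuron markers, 2 were higher and 2 lower in cortex (median 0.03), while 3 were higher in striatum (median 0.61). Of 6 amygdala and ventral forebrain markers, 0 were higher in amygdala by limma and 2 were lower. The numbers of probe sets past both thresholds were 53 in cortex, 44 in striatum, 112 in hippocampus, 79 in amygdala and 62 in accumbens. Without both arrays that stood apart, amygdala had 122.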

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

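The tests of a wrong line, a swap or cortex tissue for the arrays of cortex iP 5 and amygdala iP 1, and of other probe sets of called genes, were chosen only after the result was seen. The 10 groups of arrays were each tested on 4 measures for an array far from the rest, and 8 of the 40 tests found one, where chance gives about 1 in 20. These 8 are not independent: they fell on 5 arrays in 5 groups, and 4 of them on cortex iP 5. Cortex iP 5 had a median signal of 251, a Gapdh ratio of 6.14 and a beta-actin ratio of 4.42 (3′ to 5′, log2), and a mean correlation with its own group of 0.812. Accumbens iNP 7 had a median signal of 382. Amygdala iP 2 had a beta-actin ratio of 1.13. The mean correlation with the own group was 0.925 for accumbens iP 4 and 0.951 for striatum iP 2.

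A test of degraded RNA for the array of cortex iP 5, set beforehand on a separate control, hexokinase, missed: its 3′ to 5′ ratio of 2.85 (log2; 2.93 without the floor of 16) was below the 3.91 of accumbens iP 4. Degraded RNA is left open for a reason found only after that value was seen. The 3′ signal was 115, so with the floor the ratio could not have exceeded 2.85. The 5′ signal was 15.1, and the medians of the other arrays were 2131 (3′) and 1195 (5′). The high Gapdh and beta-actin ratios go the way of degraded RNA. They also marked the array out, so they are no separate check. An array of the other line is argued against, since the array scored 0.45 toward iP on line probe sets chosen without this animal and 12 of 13 strong ones lay nearer the iP mean, with Hs6st1, at the iNP level of 5.70, the exception. The Gapdh and beta-actin ratios, 70.6 and 21.4 on the linear scale against at most 1.36 and 2.18 on the other 58 arrays, do not bear on a swap with the amygdala array of iP animal 1, since exchanged labels leave a ratio as it is. For the regional profile, a swap cannot be told apart from degraded RNA, and both may hold: the cortex-high genes lay at -1.26, inside the range of the other amygdala arrays (-1.48 to -0.07) and outside that of the other cortex arrays (0.69 to 1.06), the amygdala-high genes lay at -0.40, between the cortex (-0.96 to -0.51) and amygdala (0.55 to 0.92) ranges, and the whole profile correlated across probe sets at 0.311 with amygdala and -0.109 with cortex.

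The amygdala array of iP animal 1 resembled cortex. A swap with the cortex array of the same animal is argued against, since that array scored -1.28, inside the cortex range. Cortex tissue in the sample or a cortex array under this label stays open. Over the 5144 probe sets outside the score, the array correlated best with the cortex profile (Spearman rho 0.290 across probe sets). That was above the other amygdala arrays (at most -0.0465) and just below the other cortex arrays (0.300 to 0.514). Its rho with amygdala, -0.138, lay inside the range of the other cortex arrays (-0.275 to -0.108). The other amygdala arrays lay between 0.0767 and 0.666. Its amygdala-high genes (-0.68) and cortex-high genes (0.84) lay inside the ranges of the other cortex arrays. These genes make up the score that picked the array out, so they are no separate check. Whether the array came from the other line cannot be told apart. Its line score was -0.10, which made it the only array of 59 not on the side of its line. On the same 200 probe sets, the other arrays of animal 1 scored 0.03 (hippocampus), 0.07 (cortex), 0.16 (accumbens) and 0.23 (striatum). Low scores were thus not limited to this array. Of 16 strong line probe sets, 12 lay nearer the iP mean, exactly the limit that had to be exceeded to argue against the other line. Among those, Hs6st1 (11.30, iNP amygdala arrays 5.90 to 6.87), Akap11 (11.18, iNP 8.50 to 9.24) and Gsta4 (9.16, iNP 10.66 to 10.86) lay outside the iNP range toward iP.

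Line differences at a single probe set may come from a sequence difference under the probes, in place of a difference in transcript level. Of 22 called genes with another tested probe set on another sequence record, taken once each, the other probe set differed the same way at an unadjusted p under 0.05 in 11, or 50% (exact 95% binomial interval 28.2 to 71.8). That interval is too wide to exclude the explanation or bear it out for the called genes as a set, so sequence and transcript level cannot be told apart. In 3 of the 22 the other probe set was itself called in the same direction. The count does not weigh size: the other Pgk1 probe set differed by 0.12 against 1.12, and that of Phgdh by -0.53 against -0.62. Hs6st1, Akap11, Mfsd10, Arpc4, Tmtc3, Ddx42, Paqr3 and Slc5a3 each had 1 tested probe set, so the test does not cover them. No biological explanation other than the line itself was tested.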

How the results depend on the processing

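Settings that leave out the 2 arrays in doubt, use an animal batch, use the earlier variance trend or fit all arrays with no replicate block in single regions were chosen after seeing the data. No result reversed. For the named genes and the 5 lists past the threshold together, alternatives fixed before the data were examined kept the call in 1501 cases and lost it in 59. Added alternatives kept 299 and lost 16. Named genes were the largest calls with no overlap between the lines, which favours keeping a call. Without the filter on dim probe sets the counts against the other regions were 98 (cortex), 88 (striatum), 181 (hippocampus), 135 (amygdala) and 132 (accumbens), with more probe sets tested. With 60% dropped, accumbens had 19 line calls. Array weights gave 37 in cortex and the Gapdh ratio as a covariate 30. With all arrays in one fit and the animal as a random replicate block, cortex had 56, amygdala 59 and accumbens 51; with all arrays and no replicate block they had 57, 58 and 55, so these moves came with fitting all arrays together and not with the block. Over all regions, all arrays gave 179 with the random block and 230 with no replicate block. For the interaction and for each region against the others, leaving out the block moved no count by over 1.5 times. The cause of the other moves was not tested. Cortex had 24 line calls without iP animal 5, also with both arrays left out, where amygdala against the others had 122. Over all regions there were 143 calls without the cortex array, 162 without the amygdala array and 167 without both. Lists past the threshold fell from 5 to 0 with an estimated correlation; quantile normalization kept 4 of the 5.

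Leaving out 1 animal at a time gave 9 to 24 calls in cortex, 37 to 45 in striatum, 25 to 36 in hippocampus, 22 to 51 in amygdala (22 without iP animal 4), 19 to 37 in accumbens (19 without iNP animal 9), 107 to 200 over all regions and 0 for the interaction. Animals 1, 2, 7 and 8 differed from the others in 776 probe sets, a grouping seen in the data and in no label. It holds both lines. Their mean beta-actin 3′ to 5′ ratio per animal (log2) was 0.75 to 0.82, against 0.28 to 0.48 in the others (without cortex iP 5). The amygdala arrays nearest another region (iP 1, iNP 7 and iNP 8) came from these animals, while that of iP 2 was nearest amygdala. The cause of the grouping was not tested. With the grouping as a term, 173 probe sets were called over all regions. Within those 4 animals 16 were called, and within the other 8 animals 149. The earlier variance trend gave 137. Probe sets near the floor of 16 give compressed differences.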

Other observations

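The tests of neighbouring genes without the RT1 genes and under the earlier variance trend, and the reading of the neighbour result as open, were chosen only after the result was seen. By limma over all regions, none of 15 GABA genes (1 rose when adjusted over the list alone), 22 glutamate genes (1 fell when adjusted over the list alone), 15 dopamine and monoamine genes, 10 serotonin genes or 5 opioid genes was called over all probe sets. Examples are Gad1 (-0.09 ± 0.07), Slc1a3 (-0.03 ± 0.05), Maob (0.02 ± 0.05) and Penk (0.01 ± 0.07). In alcohol and aldehyde metabolism, Aldh1a1, an aldehyde dehydrogenase, rose by 0.31 and catalase, Cat, by 0.38, 2 of 12 genes, also when adjusted over the list alone. Of 30 antioxidant genes Gstm7 rose by 0.21, while Gsta4 fell by 1.17.

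Of 9 microglia and macrophage markers, Lyz2 rose by 0.54 and P2ry12 fell by 0.77; adjusted over the list alone 1 rose and 2 fell. None of 13 astrocyte or 9 myelin and oligodendrocyte markers was called. In amygdala, the 14 medium spiny neuron markers were lower in iP by camera with a median of -0.28 (adjusted p = 0.00454; adjusted p = 0.604 with an estimated correlation). One of the 6 iP arrays there is the one that scored -1.06 toward cortex. Of the 6 iNP arrays there, those of animals 7 and 8 correlated better with the accumbens profile (Spearman rho 0.263 and 0.232 across probe sets) than with amygdala (0.103 and 0.145). All 14 of these markers were higher in accumbens than in the other regions, so these arrays limit the reading of this list as a line difference. In cortex, the myelin list had a median of 0.22 (adjusted p = 0.0244; adjusted p = 0.606 with an estimated correlation), with iP 5 among its arrays. In accumbens, 3 further lists passed by camera with no member called. The 22 glutamate receptor and transporter genes were lower, with a median of -0.13 (adjusted p = 0.0459; adjusted p = 0.499 with an estimated correlation). The 13 genes of NF-kappa B and inflammation were higher, with a median of 0.20, and 1 rose when adjusted over the list alone (adjusted p = 0.0459; adjusted p = 0.27 with an estimated correlation). The 10 meninges and fibroblast markers were higher, with a median of 0.26 (adjusted p = 0.0459; adjusted p = 0.43 with an estimated correlation).

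The lists that were lower over all regions also passed in some single regions. Antigen processing was lower in striatum (adjusted p = 0.0139; adjusted p = 0.645 with an estimated correlation), hippocampus (adjusted p = 0.00627; adjusted p = 0.865 with an estimated correlation) and amygdala (adjusted p = 0.0046; adjusted p = 0.249 with an estimated correlation). Blood cell transcripts were lower in cortex (adjusted p = 0.0178; adjusted p = 0.606 with an estimated correlation), striatum (adjusted p = 0.0427; adjusted p = 0.688 with an estimated correlation) and amygdala (adjusted p = 0.0046; adjusted p = 0.604 with an estimated correlation). Endothelial genes were lower in amygdala (adjusted p = 0.0287; adjusted p = 0.295 with an estimated correlation). The preference candidates were lower in cortex (adjusted p = 0.0178; adjusted p = 0.258 with an estimated correlation), striatum (adjusted p = 0.0238; adjusted p = 0.292 with an estimated correlation), amygdala (adjusted p = 0.0138; adjusted p = 0.249 with an estimated correlation) and accumbens (adjusted p = 0.0459; adjusted p = 0.27 with an estimated correlation). In each of these regions Gsta4 was the only candidate called (-1.08, -1.35, -1.18 and -0.88). Npy was lower in each and not called. Grm7, Crh, Pdyn and Neurod1 were not called and had mixed signs, so these list results lean on 1 gene.

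Chance assignment of animals to lines was tested with 100 splits each, the real one included. For cortex 1 split (the real one, 12 calls; highest other 1), striatum 1 (44; 1), amygdala 1 (38; 15), accumbens 1 (30; 2) and all regions 1 (139; 2) gave as many calls, which argues against chance as far as 100 splits can show. For hippocampus 2 did: another split called 62 against the real 35, and it put 1 of animals 1, 2, 7 and 8 on one side and 3 on the other. For the interaction the real count by limma was 0 (242 at an unadjusted p under 0.05), so all 100 splits gave at least as many by construction, which says nothing about chance. One split, with those 4 animals together, gave 20; the same test made 14.4 false calls per simulated run where each group kept its own spread, so that count is not read as a structure of the samples. With region labels permuted within animals, only the real labels (1 of 100) gave as many calls for each region; the highest others were 7, 5, 4, 13 and 2 for cortex, striatum, hippocampus, amygdala and accumbens.

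A hypothesis is that fixed chromosome segments carry several line differences. Among 3165 tested genes placed in order, 7 neighbouring pairs were both called, against a mean of 3.18 and a 95th percentile of 6 in 10000 random draws (permutation p = 0.0373); under the earlier variance trend, the form in which the test was first seen, there were 8 (permutation p = 0.0126). Of the 7 pairs 2 hold RT1 genes: RT1-CE16 with RT1-CE12, and RT1-CE12 with Ddx39b, which is outside that family. Another candidate explanation is that probe sets of the RT1 family read each other's transcripts. Leaving out the RT1 genes also takes out the pair with Ddx39b. Without the RT1 genes 5 pairs remained, against a mean of 2.94 and a 95th percentile of 6 (permutation p = 0.174), and 6 under the earlier trend (permutation p = 0.0696). The call was lost while 5 of the 7 pairs remained, so segments and shared probe sets cannot be told apart.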
